A study of Homo sapiens with 14 samples.

How the data were processed

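RNA was sequenced from cultured human hepatic stellate cells, the vitamin A storing cells of the liver that turn into matrix-producing myofibroblasts after injury. The labels describe 14 libraries, 8 from Normal cells and 6 from cells of alcoholic liver disease (ALD). Pairs of libraries share a code in their titles, and such a pair was treated as 1 unit, which gave 4 Normal and 3 ALD units of 2 libraries each. The labels do not state that the codes are separate donors, so p-values measure only the spread between these units. Titles also end in P0, P1 or P2, which the labels do not spell out. All 3 ALD units and 2 Normal units carry P0, and the other 2 Normal units carry P1 or P2. The protocols in the labels describe serum starvation and several added factors, among them TGF-beta and IL-6, without saying which library received which, so no treatment was compared. Nor do they say whether the 2 libraries of a unit were treated alike, so that a unit can be a mean over treatments, and a difference between its libraries can be one of treatment.

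The authors deposited 1 table of normalized signal for 19672 gene symbols, in which read counts were divided by 1 factor per library, as the values show. Per the submitters' processing notes, TopHat 1.4.1, SAMtools, HTSeq 0.6.0, DESeq and DESeq2 1.6.3 were used with the hg19 build. The gene annotation, strand setting and filters are not given in the sources used here. In the table, 4 columns matched no sample of the labels and were not used. Within each library the deposited values were whole multiples of 1 step, to a tolerance of 0.01, for 100% of the 225464 non-zero values, so whole reads were recovered. Library totals ran from 7649913 to 21930389 reads and the factors from 0.490 to 1.29. Scaling by 1 factor per library leaves trends with GC content in place. Overlapping genes cannot be separated without the strand setting, and near-identical genes, such as those of the HLA class II family, can share reads.

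Y-linked genes, XIST and TSIX, 23 in all, were removed before any test, which left 19649 genes. The 2 libraries of a unit were averaged on the linear scale. Genes with a unit value of at least 10 in at least 3 of the 7 units were tested, 13233 in all. ALD was compared with Normal by limma 3.58.1 with a mean-variance trend on log2(value + 1), in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference on this scale understates the change of genes with low values. The 4 Normal units were also compared among themselves, 2 with suffix P1 or P2 against 2 with P0.

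Before the data were examined, 20 gene lists with 364 genes were fixed, of which 349 were found in the table, some under an older symbol. The list of mitochondrially encoded mRNAs matched no gene, and 19 lists were tested. These were collagens and matrix proteins, contractile myofibroblast genes, matrix remodelling and crosslinking, TGF-beta signalling and targets, quiescent stellate cell markers, markers of macrophages, hepatocytes, endothelial cells, cholangiocytes, lymphocytes, and portal fibroblasts and mesothelium, cell cycle, cytokines and NF-kB targets, interferon-stimulated genes, MHC class II presentation, cholesterol synthesis, ethanol and aldehyde metabolism, NRF2 antioxidant targets, and the unfolded protein response. The macrophage list and some matrix genes hold names that the study is known to have put forward from these samples. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean over all 35 splits of the 7 units, which cannot give a p below 0.0286.

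The genes named in the text follow a rule fixed before the data were examined. It took the 10 genes in each direction with the largest difference among those past the threshold, with a mean of at least 50 in the higher group and no overlap of the groups, and filled up by the smallest unadjusted p where too few passed. It also took up to 4 members of each list with the smallest unadjusted p, and in any case a few stellate cell genes, among them ACTA2, COL1A1, TIMP1, PDGFRB and LRAT. Some of the genes the rule took are not reported here. Further list members, given as levels of other cell types or of single units, and any gene said to have been chosen after its values were seen fall outside the rule. Symbols are as in the table. No coordinates are given, because the reference at hand (GRCh38) is of another build than the authors'. It served for gene names, for excluding Y-linked genes and for the GC content of transcripts, which 94.6% of the tested genes had.

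The alternatives fixed in advance were another pseudocount, other filters and scalings, other ways of handling the paired libraries and the suffix, other estimates of the spread, leaving out each unit in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads summed per unit. Values with the GC trend of each library removed (lowess, span 0.3), edgeR without ALD 1, and the comparison of Normal units without each unit were added after seeing the data. The limma test was tested on simulated data. In 20 simulations of ALD against Normal on 13080 genes, with 200 changed genes in each, it recovered 9% of the genes changed 2-fold, 66.4% of those changed 4-fold, 88.7% of those changed 8-fold and 95.3% of those changed 16-fold, with 8.45 false calls per simulation. Each simulated change was given to all ALD units alike. The shares recovered therefore do not hold for genes raised mainly in 1 ALD unit. MMP9, by far the highest in ALD 1, differed by 7.03 and missed limma's threshold (adjusted p = 0.942). A list of 20 genes shifted 2-fold passed camera in 20 of 20 simulations, and an unshifted list had a p under 0.05 in 1 of 20. Simulated genes varied independently, so these counts do not show how camera at its preset correlation behaves on lists whose members vary together. The correlation estimated in the data was 0.911 for the cell cycle list and 0.784 for the macrophage list. Figures were drawn with matplotlib 3.10.9.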

Results

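Gene expression was measured by RNA sequencing in cultured human hepatic stellate cells labelled Normal (4 units) or alcoholic liver disease, ALD (3 units), each unit being the mean of 2 libraries that share a title code. Libraries held 7649913 to 21930389 reads, the fewest in a library of ALD 1, and 15804 to 16515 genes with at least 1 read. Values are deposited normalized read counts, and differences are ALD minus Normal of log2(count + 1), given with their standard error. The most abundant gene of a library, which was fibronectin (FN1), collagen I (COL1A1), ferritin light chain (FTL) or elongation factor EEF1A1, took 1.33% to 7.17% of its reads.

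The design asks how stellate cells from ALD differ from Normal stellate cells. Macrophage markers were higher in ALD as a group, and by far the most in ALD 1. Lysozyme (LYZ) stood at 2099 normalized counts in ALD 1, 78.8 in ALD 2 and 83.8 in ALD 3, against 4.85 to 19.8 in the 4 Normal units. The scavenger receptor MSR1 stood at 2603, 19.8 and 60.2 against 0.893 to 7.57, and the myeloid transcription factor SPI1 at 1371, 15.6 and 23.9 against 0.490 to 2.84. The lysosomal CD68 was at 12925 in ALD 1, but its 1676 in ALD 2 and 1400 in ALD 3 lay within the 852 to 2834 of the Normal units. The groups did not overlap in 6 of the 13 members that could be tested, of 24, against 5.47% of all tested genes. MSR1, SPI1 and C1QB reached at most 9.76 in a Normal unit, so the filter kept them only with all 3 ALD units at 10 or more. Their lack of overlap was thus fixed by the filter, and they also enter the list mean and its tests. All 13 had a higher mean log2 value in ALD (median difference 3.89), of which 0 passed limma over all genes and 8 adjusted over the list alone. The study put forward some of these names from these samples, so the list is not independent evidence of its direction. Camera gave an adjusted p = 4.26e-14 at its preset correlation, and an adjusted p = 0.618 with an estimated correlation. The list mean was higher in all 3 ALD units (5.61 to 11.2) than in all 4 Normal units (3.56 to 4.82), with an exact permutation p = 0.0286, the smallest this design allows, and an adjusted p = 0.543 over 19 lists. Without ALD 1 the median was 2.04 (preset camera adjusted p = 6.92e-16, with 5.18e-29 to 3.31e-06 over 21 settings).

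**Figure D1:**
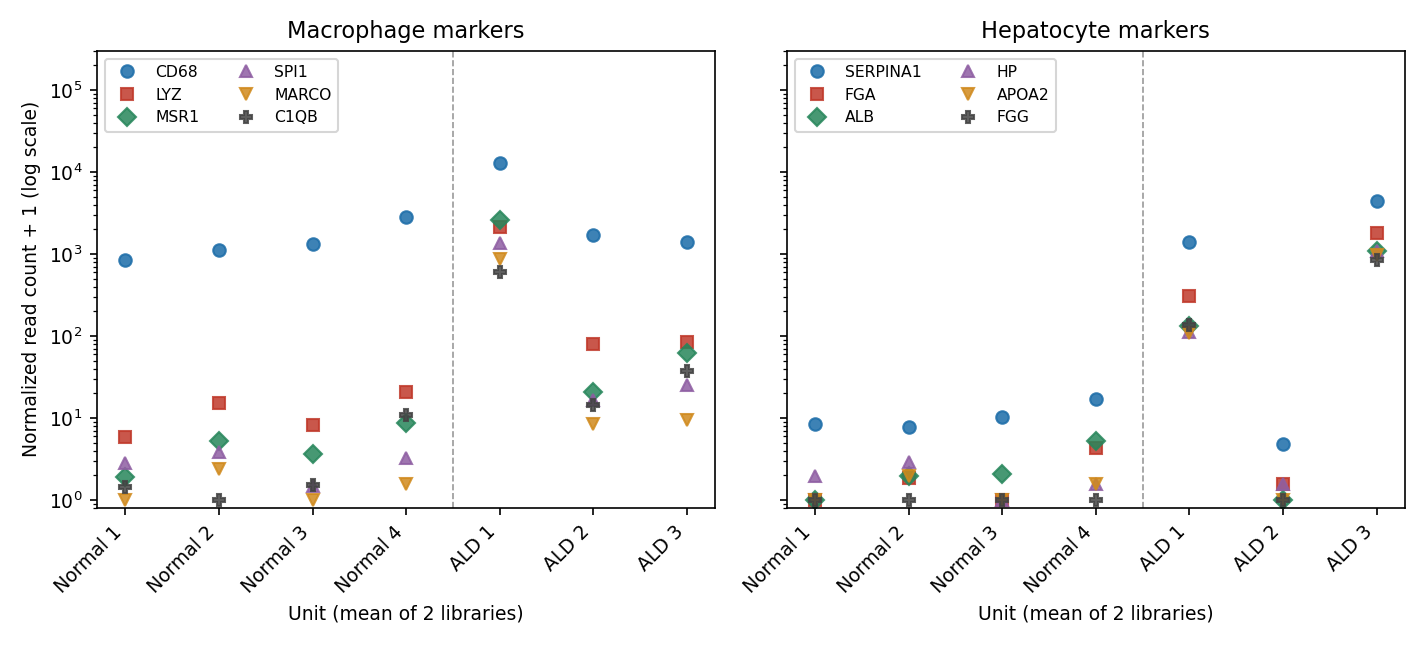
Normalized read count + 1, on a log axis, of 6 macrophage markers (left) and 6 hepatocyte markers (right) in each of the 7 units, with 1 point per gene and unit and a dashed line between Normal and ALD. LYZ reached 2099 in ALD 1, and FGA reached 1804 in ALD 3.

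Genes of MHC class II antigen presentation were also higher in ALD, again the most in ALD 1, where macrophage markers were highest. The list mean on the log2 scale was 8.88 in ALD 1, 6.24 in ALD 2 and 7.08 in ALD 3 against 3.95 to 6.35 in Normal units, so that ALD 2 lay inside the Normal range. The invariant chain CD74 averaged 656.4 ± 790 (SD, n = 3) in ALD and 88.9 ± 69.1 (SD, n = 4) in Normal units, a difference of 2.58 ± 1.01. The peptide-loading chaperone HLA-DMA differed by 1.37 ± 0.50, HLA-DPA1 by 1.02 ± 0.36 and HLA-DRA by 3.82 ± 1.44. HLA-DRA stood at 358.6 in ALD 1, while its 48.4 in ALD 2 and 53.9 in ALD 3 lay within the 0 to 54.0 of the Normal units, and the groups overlapped in each of the 6 tested members. All 6 tested members were higher (median 1.98), 0 of them past limma's threshold over all genes and 4 adjusted over the list alone. The preset camera adjusted p = 1.69e-05, against an adjusted p = 0.618 with an estimated correlation, and the exact permutation p = 0.114. Without ALD 1 the median was 0.97 (preset camera adjusted p = 0.000136, with 1.21e-09 to 0.0147 over 21 settings).

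Cholesterol synthesis genes were higher in ALD in 21 of 21 tested members, by a median of 0.44. SREBF2, a transcription factor that drives the pathway, differed by 0.39 ± 0.17, the decarboxylase MVD by 0.55 ± 0.34, the sterol-responsive INSIG1 by 0.63 ± 0.39 and the demethylase CYP51A1 by 0.55 ± 0.38. None of the 21 passed when adjusted over the list alone or over all genes. The preset camera adjusted p = 2.73e-05, against an adjusted p = 0.714 with an estimated correlation. The exact permutation p was 0.371, and the highest list mean was in Normal 2 (10.0), followed by ALD 3 (9.97) and ALD 1 (9.81), the 2 units with hepatocyte transcripts. Normal 4 had the lowest list mean (8.53), and without it the median was 0.16 and the call was lost (adjusted p = 0.0659, with 3.29e-12 the lowest over 21 settings).

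Interferon-stimulated genes were higher in ALD in 13 of 20 tested members, with a median of 0.25. IFI27 averaged 539.9 ± 207 (SD, n = 3) in ALD and 205.1 ± 81.7 (SD, n = 4) in Normal units, a difference of 1.38 ± 0.37. BST2, which tethers enveloped viruses to the cell, averaged 1867 ± 563 and 674.1 ± 327, a difference of 1.58 ± 0.42 with no overlap of the groups. MX2 differed by 1.33 ± 0.66 and IRF7 by 0.60 ± 0.35, and 0 members passed when adjusted over the list alone or over all genes. The preset camera adjusted p = 0.0121, against an adjusted p = 0.714 with an estimated correlation, and the exact permutation p = 0.343. ALD 1, the unit highest in macrophage markers, also had the highest interferon list mean (8.27). The call was lost without it (median 0.11, adjusted p = 0.420) and without Normal 4 (median 0.03, adjusted p = 0.210), with 1.69e-05 the lowest over 21 settings.

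Cytokines and NF-kB targets were lower in ALD in 12 of 16 tested members, with a median of -0.76, and the list mean was highest in Normal 4. The neutrophil chemokine CXCL1 stood at 2878 in Normal 4 and at 30.2 to 203.7 in the other Normal units, against 14.0 to 49.0 in ALD. CXCL6 stood at 2268 in Normal 4 and at 37.0 to 156.1 in the other Normal units, against 16.6 to 118.9 in ALD. LIF differed by -1.16 ± 0.56 and IL1A by -1.67 ± 0.80, and 0 members passed when adjusted over the list alone or over all genes. The preset camera adjusted p = 0.0322, against an adjusted p = 0.778 with an estimated correlation, and the exact permutation p = 0.429. The call was lost without Normal 4 (median -0.32, adjusted p = 0.457), without ALD 2 (median -0.45, adjusted p = 0.475), without Normal 2 (median -0.95, adjusted p = 0.0518) and without a mean-variance trend (adjusted p = 0.0506), with 1.25e-06 the lowest over 21 settings. With fry the adjusted p = 0.835 for each of the 5 lists that passed the preset camera test.

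**Figure D2:**
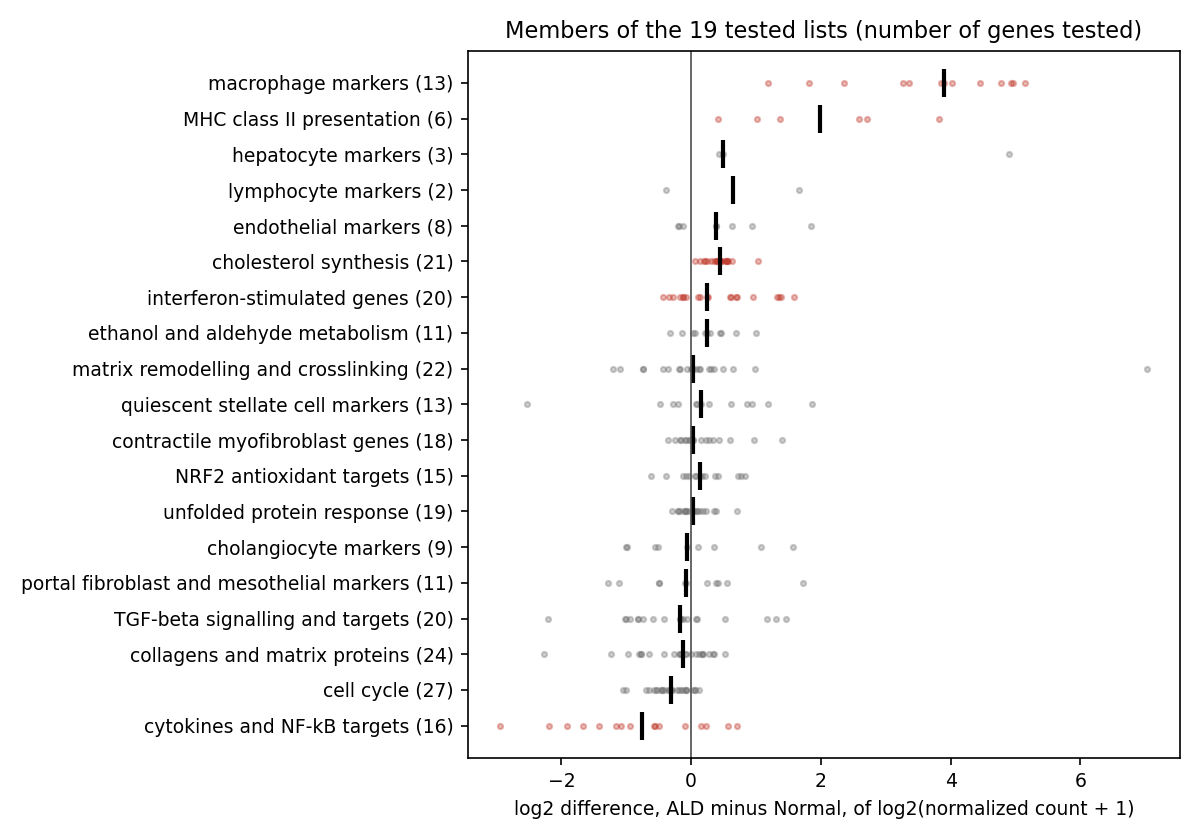
The log2 difference, ALD minus Normal, of each tested member of the 19 lists (points) with the list median (black bars), lists being ordered by their mean difference and followed by the number of genes tested. The 5 lists in red had a preset camera adjusted p under 0.05, with medians from -0.76 for cytokines to 3.89 for macrophage markers.

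Lists of stellate cell activation did not pass the test, and ACTA2, COL1A1, TIMP1 and PDGFRB overlapped between the groups. Smooth muscle actin (ACTA2) averaged 66997 ± 37829 (SD, n = 3) in ALD and 51976 ± 17014 (SD, n = 4) in Normal units, a difference of 0.23 ± 0.46 with a 95% interval from -0.82 to 1.27. COL1A1 differed by 0.07 ± 0.59, with a 95% interval from -1.28 to 1.43. The metalloproteinase inhibitor TIMP1 differed by 0.49 ± 0.41 and the PDGF receptor PDGFRB by 0.29 ± 0.41, and limma's adjusted p of these 4 genes was 0.984 or more. LRAT, the retinol-esterifying enzyme of quiescent stellate cells, reached at most 2.04 in a unit and was not tested. Collagens and matrix proteins had a median of -0.13 (preset camera adjusted p = 0.377), with the proteoglycan VCAN at -1.24 ± 0.50 and tenascin C (TNC) at -2.28 ± 1.01. Contractile genes had a median of 0.03 (adjusted p = 0.377), with the myosin light chain MYL9 at 0.42 ± 0.27. Matrix remodelling and crosslinking genes had a median of 0.02 (adjusted p = 0.591). In that list the gelatinase MMP9 stood at 33992 in ALD 1, 328.9 in ALD 2 and 100.7 in ALD 3 against 2.62 to 15.3 in Normal units. TGF-beta signalling and targets had a median of -0.17 (adjusted p = 0.369), with ID3 higher in all 3 ALD units (1.17 ± 0.30) and TGFBI lower in all 3 (-1.02 ± 0.32), both at a limma adjusted p = 0.942. Quiescent stellate cell markers had a median of 0.15 (adjusted p = 0.369), with RELN at 1.87 ± 0.82 and VIPR1 at -2.53 ± 1.02. Without ALD 2, the collagen (median -0.48, adjusted p = 0.000891), TGF-beta (-0.63, adjusted p = 0.00452) and quiescence lists (0.80, adjusted p = 0.00465) passed the preset camera test, while over all units each had an adjusted p = 0.778 with an estimated correlation.

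**Figure D3:**
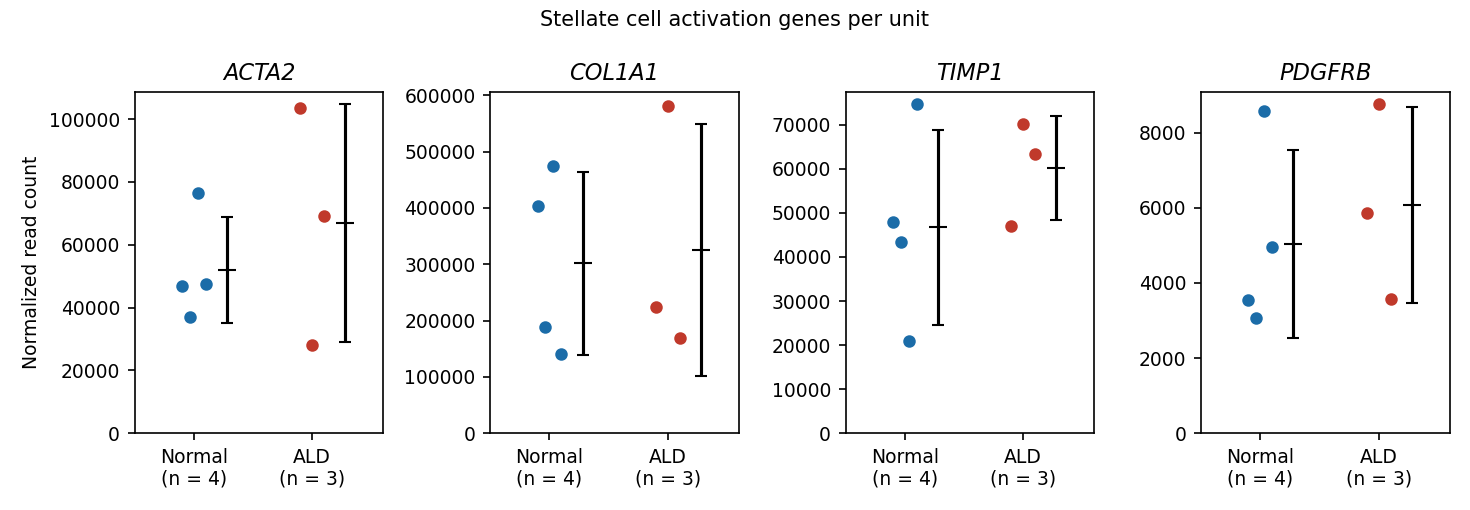
Normalized read counts (vertical axes, starting at 0) of 4 stellate cell activation genes in each Normal and ALD unit (points), with the mean and SD of each group beside them (n = 4 and n = 3). The groups overlap for each gene, as for ACTA2 with means of 66997 in ALD and 51976 in Normal units.

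Hepatocyte transcripts were present in ALD 3 and, at lower levels, in ALD 1. Albumin (ALB) stood at 1074 in ALD 3, 130.3 in ALD 1 and 0 in ALD 2, with 0 to 4.17 in Normal units. The fibrinogen chain FGA stood at 1804, 301.7 and 0.548, with 0 to 3.27 in Normal units, and the protease inhibitor SERPINA1 at 4391, 1391 and 3.78, with 6.83 to 15.9. Of 21 list members, 17 reached at least 10 times the highest Normal unit in ALD 3, 11 in ALD 1 and 0 in ALD 2. The filter left 3 members to test (median 0.50, preset camera adjusted p = 0.117), and the list passed without ALD 2 (median 2.06, adjusted p = 0.000389), with no filter (3.27, adjusted p = 2.44e-14) and with a unit mean of at least 100 (4.90, adjusted p = 4.53e-05). It also passed with the unit as a random block (0.50, adjusted p = 0.0387) and with the lower-numbered libraries (0.67, adjusted p = 0.0417). These calls are at the preset correlation, and with an estimated correlation, over all units, the adjusted p = 0.674 for hepatocyte and endothelial and 0.778 for lymphocyte markers. Endothelial markers had a median of 0.38 (adjusted p = 0.134), with von Willebrand factor (VWF) at 255.1 in ALD 1 and 14.4 to 30.0 in the other units, and passed without ALD 2 (median 0.88, adjusted p = 0.0295) and with no filter (0.70, adjusted p = 0.000100). Without ALD 1 the endothelial median was 0.07 (adjusted p = 0.504). Lymphocyte markers had a median of 0.64 over 2 tested genes (adjusted p = 0.686) and passed with no filter (0.67, adjusted p = 0.00579), but the median was -0.13 without ALD 1, where the chemokine CCL5 stood at 393.1, and -0.14 against the Normal units with P0 alone. The T cell gene CD3E reached at most 4.68 in a unit. Cholangiocyte markers had a median of -0.06 (adjusted p = 0.812). Portal fibroblast and mesothelial markers had a median of -0.08 (adjusted p = 0.707), with the mesothelial gene UPK3B at 220.3 in ALD 3 and 3.78 to 11.5 in the other units.

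Cell cycle genes had a median of -0.31, with 23 of 27 members lower in ALD, and did not pass (adjusted p = 0.142). Their list mean was lowest in Normal 4 (5.84) and ALD 2 (6.36), against 7.42 to 8.68 in the other units. Topoisomerase TOP2A averaged 145.6 ± 110 (SD, n = 3) in ALD and 348.7 ± 298 (SD, n = 4) in Normal units. The list passed without Normal 4 (median -0.90, adjusted p = 1.77e-11) and without ALD 3 (median -0.71, adjusted p = 0.000434), and with the lower-numbered libraries (median -0.28, adjusted p = 0.0348), and its median was 0.12 without ALD 2 (adjusted p = 0.475). With an estimated correlation, over all units, its adjusted p = 0.778. Ethanol and aldehyde metabolism genes had a median of 0.25 (adjusted p = 0.0847), with catalase (CAT) at 0.45 ± 0.19 and the ethanol-oxidizing CYP2E1 at 1.00 ± 0.53, and passed without ALD 2 (median 0.39, adjusted p = 0.0156), Normal 1 (0.39, adjusted p = 0.0398) or Normal 2 (0.43, adjusted p = 0.0114), and with the lower-numbered libraries (0.32, adjusted p = 0.0417). NRF2 antioxidant targets had a median of 0.14 (adjusted p = 0.154), with FTL higher in all 3 ALD units at 0.77 ± 0.31, and passed without ALD 2 (median 0.28, adjusted p = 0.0298) or Normal 2 (0.25, adjusted p = 0.0170). The unfolded protein response had a median of 0.03 (adjusted p = 0.574), with calreticulin (CALR) at 0.36 ± 0.27, and passed against the Normal units with P0 alone (median 0.32, adjusted p = 0.0166). With an estimated correlation, over all units, the adjusted p = 0.674, 0.746 and 0.814 for these 3 lists.

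Gene by gene, limma called 0 of 13233 genes, and 688 had an unadjusted p under 0.05, 247 higher and 441 lower in ALD. EdgeR called 0, with 798 at an unadjusted p under 0.05, and DESeq2 called 14, 11 higher and 3 lower, with 864. The groups did not overlap in 724 genes, 5.47% of those tested, against 5.71% by chance. The 10 genes taken by smallest p in each direction all missed limma's threshold, at an adjusted p = 0.942. Among the higher ones, the heparan sulfate sulfotransferase HS6ST1 averaged 977.6 ± 170 (SD, n = 3) in ALD and 546.6 ± 44.5 (SD, n = 4) in Normal units (difference 0.83 ± 0.17), and OPN3 (1.22 ± 0.27), STARD5 (1.03 ± 0.24), CECR1 (2.43 ± 0.57) and the linker histone HIST1H1C (0.83 ± 0.20) were also higher in each ALD unit than in any Normal unit. The other 5, TM7SF4, APOC1, SDS, CD53 and TREM2, stood at 1065 to 3518 in ALD 1 and at 18.1 to 278.2 in ALD 2 and ALD 3. In Normal units these 5 stood at 0 to 14.3. All but APOC1 reached at most 2.61 in a Normal unit, so the filter kept them only with all 3 ALD units at 10 or more. Their lack of overlap was thus fixed by the filter. Among the lower ones, ARHGAP29 averaged 162.9 ± 87.2 in ALD and 574.9 ± 157 in Normal units (-1.89 ± 0.37), the hyaluronan-binding TNFAIP6 87.1 ± 27.4 and 239.2 ± 57.1 (-1.46 ± 0.29), the transcription factor RUNX2 25.6 ± 9.61 and 101.6 ± 48.4 (-1.89 ± 0.43), and the hepatocyte growth factor receptor MET 148.6 ± 120 and 504.5 ± 130 (-2.00 ± 0.47). COG6, MYBL1, BAZ2B, FNBP1L and PTPRK differed by -1.91 to -0.73. HS6ST1, OPN3, CECR1, APOC1 and SERPINA1 were among the 11 higher genes of DESeq2, and ARHGAP29, TNFAIP6 and IGFBP3, the last chosen after its values were seen, were the 3 lower ones. Without ALD 1, 254 genes had an unadjusted p under 0.05 by limma, and without ALD 2, 1169 did and 3 were called.

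The differences between the groups followed transcript GC content. Across genes, which are not independent replicates, the Spearman correlation between the log2 difference and GC content was 0.35. Genes higher in ALD at an unadjusted p under 0.05 had a median GC content of 54.3%, the lower ones 40.2% and the remaining genes 49.1%. Among the 12521 genes with a known GC content, 240 higher and 425 lower ones had an unadjusted p under 0.05. With the GC trend of each library removed, these became 328 higher and 321 lower, and 0 passed adjustment in limma.

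The Normal units with suffix P1 or P2 were compared with those with P0, 2 against 2. Cytokines and NF-kB targets were lower in the units with P1 or P2 (median -1.66, preset camera adjusted p = 1.79e-12), while collagens and matrix proteins (median 0.40, adjusted p = 0.000665) and unfolded protein response genes (median 0.41, adjusted p = 4.07e-06) were higher. Cell cycle genes were higher (median 0.62, adjusted p = 0.000665), macrophage markers lower (median -0.79, adjusted p = 0.0202), and the 2 tested lymphocyte markers lower (median -1.55, adjusted p = 0.0226). With an estimated correlation none of the 6 lists passed (adjusted p = 0.433, and 0.738 for cell cycle), and fry passed 0. Limma called 0 genes, with 355 at an unadjusted p under 0.05. Without Normal 4 the cell cycle genes were lower (median -0.73, adjusted p = 8.64e-08), the cytokine median was -0.63 (adjusted p = 0.000241), the collagen median was 0.65 (adjusted p = 4.92e-05), and the macrophage (adjusted p = 0.237) and lymphocyte calls (adjusted p = 0.244) were lost. Without Normal 2 limma called 167 genes, the cell cycle median was 2.21 and the cytokine median was -2.67 (adjusted p = 1.33e-22). The cell cycle (adjusted p = 0.0652) and macrophage calls (adjusted p = 0.0652) were lost without Normal 3, and the lymphocyte call (adjusted p = 0.124) without Normal 1, where the cell cycle median was 1.04. All ALD units carry P0, and they were also compared with the 2 Normal units with P0 alone, which include Normal 4. At the preset correlation the ALD median was then 3.73 for macrophage markers (adjusted p = 3.31e-06) and 1.82 for MHC class II (adjusted p = 0.0135). It was 0.62 for interferon-stimulated genes (adjusted p = 0.0410), 0.46 for cholesterol synthesis (adjusted p = 0.00308) and -1.44 for cytokines (adjusted p = 2.58e-06). Normal 4 had the highest cytokine list mean, and without it the cytokine call over all units was lost. With an estimated correlation, over all units, none of these lists passed.

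The 2 libraries of a unit were mostly closer to each other than to libraries of other units. Pearson correlations of log2 values across genes were 0.959 to 0.991 within units, 0.902 to 0.963 between Normal units, 0.893 to 0.944 between ALD units and 0.861 to 0.960 between the groups. The exception was a library of Normal 1, which correlated best with a library of Normal 2. On the first principal component, with 35.9% of the variance, ALD 1 lay farthest out, at 86.4 against -49.1 to 30.0 for the other units. Within every unit the 2 libraries differed by more than sampling noise, with a chi-square per degree of freedom from 5.64 in ALD 1 to 86.8 in Normal 1. These differences also followed GC content, with Spearman correlations across genes of -0.77 in Normal 1, -0.75 in ALD 3, -0.65 in Normal 3, -0.53 in Normal 4, 0.41 in ALD 1, -0.17 in ALD 2 and -0.06 in Normal 2.

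**Figure D4:**
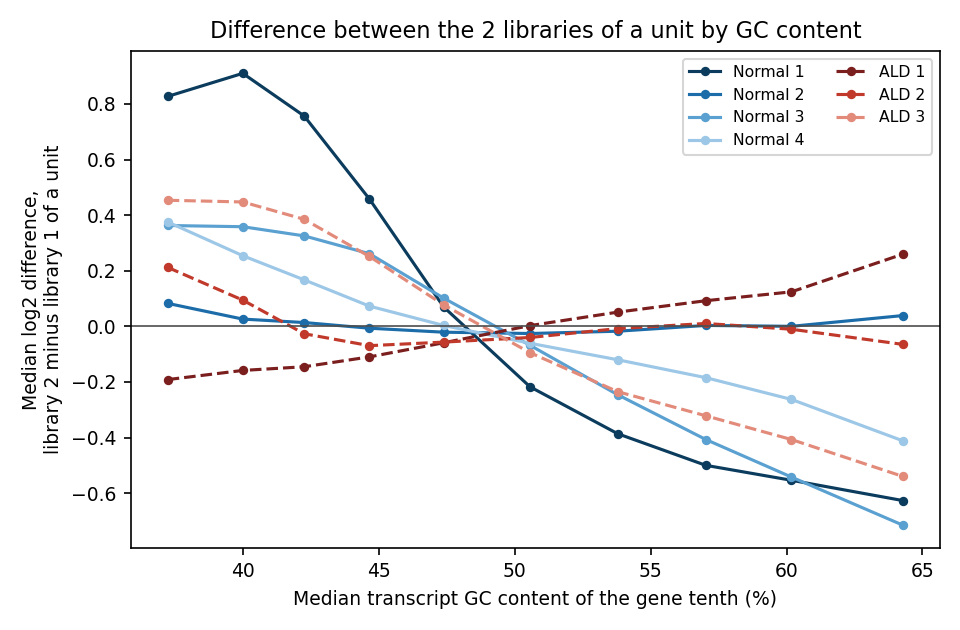
Median log2 difference between the 2 libraries of each unit (vertical axis) in 10 bins of genes by transcript GC content in percent (horizontal axis), with Normal units as solid and ALD units as dashed lines. Normal 1 falls from 0.83 in the bin lowest in GC to -0.63 in the highest, and Normal 2 stays between -0.03 and 0.08.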

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

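All tests of explanations in this part were chosen after the results were seen.

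Among 117 values examined in the 4 Normal units, 98 genes and 19 list means, 8 had 1 unit far from the other 3, where chance alone gives 5.85. The gap of that unit to its nearest neighbour, as a share of the whole range on the log2 scale, was 0.849 for SDS (0 in Normal 4, 1.98 to 2.61 in the others), 0.839 for CECR1 (138.7 in Normal 4, 36.4 to 45.2), 0.867 for ARHGAP29 (342.1 in Normal 3, 621.6 to 681.5) and 0.869 for COG6 (257.5 in Normal 3, 331.1 to 343.9). It was 0.833 for BAMBI (446.5 in Normal 3, 905.7 to 1044) and 0.871 for ACSS2 (1118 in Normal 2, 814.9 to 848.8). The mean of the TGF-beta list was 10.13 in Normal 3 and 9.87 to 9.88 in the others (gap 0.974). That of the cholangiocyte list was 7.39 in Normal 4 and 6.06 to 6.27 in the others (gap 0.845). The 5.85 assumes normally distributed values that were not selected, while the 98 genes are those the naming rule took. SDS lay at 2.61 or less, a few reads at most, in each Normal unit.

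The first pattern is the macrophage markers of the ALD units, above all of ALD 1. There 20 of the 24 list members reached at least 10 times the highest Normal unit, against 0 in ALD 2 and 1 in ALD 3. LAPTM5 at 11906 and CTSS at 4435 were among the 20. Cells of the macrophage lineage in the ALD 1 culture are a candidate source, which this count cannot test, as it restates the pattern. Reads carried over from ALD 1 would leave every gene at 1 common share, and over the 4 macrophage markers near 0 in Normal units (MARCO, MSR1, SPI1 and VSIG4) the chi-square per degree of freedom against this was 0.361 in ALD 2 and 17.8 in ALD 3, with a simulated p of 0.774 and 1e-04 for counting error alone and of 0.882 and 0.0299 once the spread between libraries of a unit is added, so carry-over cannot be told apart from expression on these few genes. A second version was run after the first was seen. It took 56 genes of the whole table, with at least 200 reads in ALD 1 in place of 100. The chi-square per degree of freedom was 8.02 in ALD 2 and 97.2 in ALD 3, with a simulated p of 0.0017 and 1e-04 with that spread (1e-04 being the smallest possible). Shares ran from 0% to 2.14% in ALD 2 and from 0.177% to 7.91% in ALD 3. For these 56 genes this argues against carry-over as the only source, while the 4 markers alone do not decide. Expression by the stellate cells themselves cannot be told apart from a mixed culture, since of the 7 units, counted from the lowest, ALD 1 ranked 7 in the contractile list mean, 2 in the collagen list and 1 in the TGF-beta and portal and mesothelial lists.

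The second pattern is the trend of the group differences with GC content. In 5 of the 7 units the 2 libraries sharing a title code differed along GC more strongly than the groups did. Single libraries are set there against group means, so the count does not show what made the group trend. Deviations from the mean of all units correlated with GC at -0.419 in Normal 1 and -0.640 in Normal 2. In the other units, of both groups, these correlations were 0.096 to 0.366. The 2 libraries of Normal 2 hardly differed along GC (-0.06). Recovery that varies between libraries with GC stays a candidate, although the labels do not exclude that these libraries were treated differently. Of the 665 genes with a known GC content and an unadjusted p under 0.05, 442 stayed there once the GC trend of each library was removed. In all, 649 of the 12521 genes had such a p then. Before that removal, 14 of the 35 splits of the 7 units gave at least the 688 genes of the real grouping. No split was run on the values without the GC trend, so how many genes chance keeps there is not known. The 442 therefore do not decide whether GC content is the whole source of the rest. A GC trend that ALD itself brings stays open, as untested.

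The third pattern is the hepatocyte transcripts of ALD 3 and ALD 1. In ALD 3, 17 of the 21 list members stood at 10 times the highest Normal unit or more. SERPINA1 stood at 4391 and FGA at 1804. Hepatocytes or their RNA in that culture are a candidate source, which this count cannot test, as it restates the pattern. Reads carried over from ALD 3 into ALD 1 would leave 1 common share, and over 10 genes the shares ran from 3.59% to 31.7%, with a chi-square per degree of freedom of 48.9 (simulated p = 1e-04 for counting error alone, the smallest possible, and 0.0987 with the spread between libraries of a unit added), so carry-over cannot be told apart from RNA of hepatocytes in ALD 1. In ALD 2, 0 of the 21 stood that high, which is part of how the pattern was seen. Expression by the ALD stellate cells stays open, as untested.

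Chance cannot be excluded for the counts of genes at an unadjusted p under 0.05 and of lists. The real grouping gave 688 such genes, where 14 of the 35 splits of the 7 units gave as many and the highest other 2301, and 5 lists, where 20 of the 35 splits gave as many and the highest other 13. With 0 genes past limma's threshold in the real grouping, 35 of the 35 splits must give as many, so that count tests nothing, and the highest other split gave 7. The split with 7 and 2301 genes, noticed as the highest, set Normal 3, ALD 1 and ALD 3 against the rest and may point to a structure of the samples other than the group, which was not tested. Their deviations from the mean of all units correlated with GC content across genes at 0.366, 0.298 and 0.114, against -0.640 to 0.108 in the other units.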

How the results depend on the processing

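The GC-corrected values, edgeR without ALD 1 and the Normal comparison without each unit were tests chosen only after the results were seen. The number of genes past the threshold was 29 with the 14 libraries as if independent, 14 by DESeq2 and 0 to 3 when 1 unit was left out (CCL26, INHBA and SERPINA1 without ALD 2, the first 2 chosen after their values were seen), and 0 in all other settings. The 688 genes at an unadjusted p under 0.05 became 1101 with no filter, 1702 with libraries as if independent, and 409 with the lower-numbered library of each unit, and edgeR's 798 became 266 without ALD 1. They became 254 to 1169 when 1 unit was left out, with 254 without ALD 1, 1169 without ALD 2 and 1102 without Normal 3. The 5 lists became 8 with no filter, 8 with the lower-numbered libraries, and 0 with an estimated correlation or with fry. They became 3 to 11 when 1 unit was left out, with 3 without Normal 4 and 11 without ALD 2. Between the Normal units 0 to 167 genes passed when 1 was left out, with 167 without Normal 2 and 5 without Normal 4, the lone unit of an arm being assumed to vary like the others. The filter changes the number of genes tested, and otherwise the cause was not tested. With a preset correlation the macrophage and MHC class II lists passed in 21 of 21 settings, cholesterol synthesis in 20, interferon in 19 and cytokines in 17. Of 2328 comparisons of named genes, 25 became calls and 2303 kept their side of the threshold. Of those of lists, 22 became calls, 17 lost theirs and 396 kept their side. Between ALD and Normal no called value changed sign, while 21 gene values and 41 list medians that were not called did, and between the Normal units the called cell cycle median of 0.62 became -0.73, also called, without Normal 4. Scaling moved the median of all genes to at most -0.04. No paired analysis was possible because the groups share no unit. Depth limits tests on few reads, such as the 83 reads behind the carry-over test of macrophage markers in ALD 2.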

Other observations

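No test in this part was planned, and the values were chosen after they were seen. Among the Normal units, Normal 4 had the highest value for 13 of 16 tested cytokines and NF-kB targets, with ICAM1, PTGS2 and IL33 the exceptions, and the lowest for 27 of 27 cell cycle genes. Its gap to the nearest unit was 0.668 and 0.656 of the range of these list means, too small to single it out by the outlier test used here. Single members were chosen for the size of their gap, and others, such as LIF at 1966 against 1758 in Normal 3, lay closer. The chemokine IL8 stood at 3568 there and at 15.2 to 155.2 in the other Normal units, the cytokine IL1B at 1642 against 69.2 to 153.5, the NF-kB target TNFAIP3 at 2364 against 309.4 to 483.0, and CCL2 at 10843 against 2216 to 3179. The proliferation gene MKI67 stood at 38.5 against 377 to 928, and the mitotic kinase PLK1 at 40.0 against 190.4 to 604.9. ALD 2 shared the low proliferation genes, with MKI67 at 86.0 and PLK1 at 48.4, but not the cytokines, with IL8 at 22.0 and CCL2 at 557.0.

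Chitotriosidase (CHIT1), a secreted enzyme of activated macrophages, reached 53761 in ALD 1, with 287.1 in ALD 2, 258.9 in ALD 3 and 2.08 to 27.7 in Normal units. The apolipoprotein APOE stood at 7563, 174.9 and 786.4 in the ALD units and at 14.1 to 169.4 in Normal units. The growth factor binding protein IGFBP3 was even across ALD at 5896 ± 385 (SD, n = 3) and higher in each Normal unit at 20804 ± 11933 (SD, n = 4), a difference of -1.65 ± 0.40 that missed limma's threshold at an adjusted p = 0.942.

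Markers of mesothelium and portal fibroblasts varied between single units. Calretinin (CALB2) stood at 892.3 in ALD 3 and 41.0 to 255.4 in the other units, and UPK1B at 123.7 in ALD 3 and 194.9 in Normal 2 against 4.68 to 15.7 in the other 5. The collagen COL15A1 stood at 3960 in ALD 2 and 36.4 to 581.5 in the other units.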
